A study of Drosophila melanogaster with 8 samples.

How the data were processed

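Small RNAs of Drosophila S2 cells, an established line of embryonic, blood-cell-like origin, were measured by sequencing of RNA size-selected to 18 to 30 nt and depleted of 2S rRNA. Adapters carried 4 random nucleotides at the ligation ends, per the labels' protocols. The labels describe 8 samples in 4 genotypes of 2 each. These are wild type, a knockout of nbr, the knockout expressing wild-type Nbr, and the knockout expressing a catalytically inactive Nbr. The titles mark the last 2 genotypes as OE, taken here as overexpression. The 3 deposited tables instead name 8 libraries by numbers from 81154 to 81161, under a header that names time points in 2 of the tables, and by a column headed time that runs from -1 to 6. None of the library numbers occurs in the labels (0 of 8 found), which give these samples no time point either. A genotype could therefore be given to a library only from its order or from its values, and neither was done. All 8 libraries were treated as unassigned, and no comparison between genotypes, replicate mean, SD or test between groups was made.

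The submitters' processing notes name cutadapt 1.7.1, Bowtie 1.2.2, Picard and the genome build dm6. Mismatch, multi-mapping and filtering settings are not given in the sources used here. The first table, as deposited, holds other values than expression, namely whole-number totals of small RNA reads and of miRNA reads per library. In the other 2 tables the authors gave, per the file headers, a signal for each hairpin arm and 5' start position. It is given once in total and once split by read length from 18 to 30 nt. Its unit, reads per 1e+06 small RNA reads of the library (RPM), was worked out from the values. The deposited score column of average RPM is the authors' mean over the 8 libraries. Multiplying each value by the library's small RNA total and dividing by 1e+06 gave whole reads on 100% of lines within 0.001 read, which identifies that total as the denominator. Reads summed over lengths equalled the arm total in every library. A second read class, marked tc by the authors, is not defined in the labels and is taken here as reads with a T-to-C mismatch.

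The tables list 289 arm and position lines for 271 arms of 177 hairpins. Hairpins with the same mature sequence, such as mir-2a-1 and mir-2a-2, list nearly the same reads at each locus. For such loci the line with the most reads was kept, and 1 further paralog line with identical reads in every library was dropped. One line was kept per mature arm at its main start position, giving 262 arms. Of these, 100 had a mean of at least 10 RPM and reads in every library, and were used for counts of arms. Paralogs that differ by few bases (miR-2a, miR-2b, miR-2c, miR-13a, miR-13b and miR-276a, miR-276b) can still share reads, so their values are uncertain. No libraries held identical values, and over the 28 pairs of libraries chi-square per degree of freedom was 21.7 to 2262, so none was counted as a duplicate.

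For each arm and library the read-weighted mean length was computed, with its counting SE. Over the libraries the median, lowest and highest values are given, and "range" means highest minus lowest. Shares carry 95% Wilson intervals. SEs and intervals cover counting error only, because amplified reads are not independent molecules. The value of 3 reads, the limit that a count of 0 allows, was 0.0910 to 0.175 RPM, and 10 RPM stood for 171 to 330 reads. The calculation was tested on simulated reads for 100 arms at the real depths: a shift of 1 nt in 20 arms gave a range of at least 0.5 nt in 20 of them, as did 0 of the 80 unshifted arms. Whole length distributions were moved, so this checks the calculation only. Sensitivity near 0.5 nt, or to a change in part of an arm's reads, was not tested.

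Hairpin positions are dm6 coordinates from the BDGP6 annotation of Ensembl release 115, in which 174 of 177 hairpin gene IDs matched. The tables give no genomic coordinates. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Before the data were examined, 14 lists of arms, the tests between genotypes and a rule for named arms were fixed. The parts of that rule that apply without a test name 4 arms expected to be substrates of Nibbler and the 5 most abundant arms. Members of the lists are named as well. Other arms were named after their values were seen, for a wide range in length or abundance. The planned linear and count models between genotypes and the list tests were not run. The minimum of 10 RPM was fixed before the data were examined. The range as a measure, the limits of 0.5 nt, of 2-fold and 3-fold and of 10% and 90% of mismatched reads, and the rule for repeated loci were chosen after the values had been seen. The alternatives tried were other abundance minimums, a length window of 20 to 26 nt, equal weights for arms, other scaling, and leaving out 1 library at a time.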

Results

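Nibbler (Nbr) is a 3'-to-5' exoribonuclease that shortens the 3' ends of some microRNAs (miRNAs) in flies. The study was set up to ask whether the length of small RNAs in S2 cells changes without Nbr, whether added Nbr restores it, and whether a catalytically inactive Nbr alters it by its presence alone. The 8 sequenced libraries held 17145872 to 32958242 small RNA reads. Of these, 6399941 to 11639214 per library were miRNA reads. The miRNA share lay between 34.7% (95% Wilson interval 34.6 to 34.7%) in library 81157 and 44.3% (44.3 to 44.3%) in library 81158. The tables' library numbers match no sample label, so the values below are given per library or as median and range over the 8 libraries. None is a comparison of genotypes. The nbr transcript itself is not measured by libraries of this size range.

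A few miRNAs made up most of the miRNA reads. Bantam-3p, a miRNA that promotes growth and blocks cell death, was the most abundant arm, with a median of 96186 reads per 1e+06 small RNA reads (RPM; 83862 to 112468). It comes from mir-ban at 3L, 642208 to 642288, plus strand, within an exon of lncRNA:CR43334. miR-14-3p, a suppressor of cell death, followed with 60521 (50351 to 76720). Its hairpin lies at 2R, 9553762 to 9553824, plus strand, within an exon of lncRNA:CR43651. miR-184-3p stood at 22514 (16176 to 29563), from 2R, 13329402 to 13329501, minus strand, within an exon of lncRNA:CR44206. By the mean over the 8 libraries, miR-2a-3p and miR-2b-3p completed the 5 most abundant arms, with 17325 (13995 to 20552) at mir-2a-1 and 15661 (12229 to 19241) at mir-2b-1. miR-8-3p lay close behind with 15006 (12689 to 18405) and exceeded miR-2b-3p in libraries 81156, 81157, 81160 and 81161. The mir-2a-1 hairpin lies in an intron of spi (2L, 19569897 to 19569972, minus strand). The mir-2b-1 hairpin overlaps an annotated exon of Btk (2L, 8258616 to 8258692, minus strand). Together the 5 arms took 59.0 to 62.5% of the reads assigned to arms, each mature sequence counted once.

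The lists of related miRNAs differed widely in level. The miR-2 family, whose members share a seed that pairs with K-box motifs, was represented by 8 of 8 arms and summed to 53173 RPM (44353 to 62288). The list of bantam, miR-14 and miR-8 summed to 172368 (154704 to 199611). The cluster of miR-277, miR-317 and miR-34 gave 13958 (12144 to 15335), that of miR-275 and miR-305 gave 7030 (5655 to 8716), and that of miR-12, miR-283 and miR-304 gave 3867 (3396 to 4574). The miR-279 family stood at 8401 (5050 to 11394) and the miR-9 and miR-79 family at 2877 (1976 to 3224). Mirtrons, which are spliced rather than cut out of introns, summed to 1106 (1044 to 1167).

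Arms typical of other tissues were near the limit of detection or low. The neuronal miR-124-3p had a median of 0.108 RPM (0.0827 to 0.334), or 2 to 11 reads per library, where 3 reads correspond to 0.0910 to 0.175. The muscle miRNA miR-1-3p had 0.190 (0.0910 to 0.450), or 3 to 12 reads, at position 56 of its hairpin. More reads, 2.16 RPM (0.883 to 3.13), began at position 61 and had a mean length of 18.8 nt in the median library. In the let-7 complex, whose miRNAs rise at metamorphosis, let-7-5p had 8.90 (5.11 to 12.5) and miR-125-5p had 1.05 (0.121 to 3.67). Of the let-7-5p reads, 74.6% were of the class taken as carrying a T-to-C mismatch. The early-embryo miR-309 cluster summed to 29.0 (23.7 to 37.7), most of it miR-6-3p with 16.9, which is also counted in the miR-2 family. The 5 listed arms of the miR-310 cluster summed to 2.71 (2.31 to 4.63). That list holds miR-992-3p but not miR-992-5p, which the tables call mature and which had 39.0 RPM (25.3 to 61.1) with a mean length of 18.2 nt in the median library. From the testis miR-959 cluster only miR-959-3p of 6 listed arms had a line, with 0.189 (0.0414 to 0.457). That list holds neither miR-959-5p nor miR-961-3p, both called mature. These had 0.207 RPM (0.0583 to 0.291, main position) and 0.240 RPM (0.152 to 0.300).

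**Figure D1:**
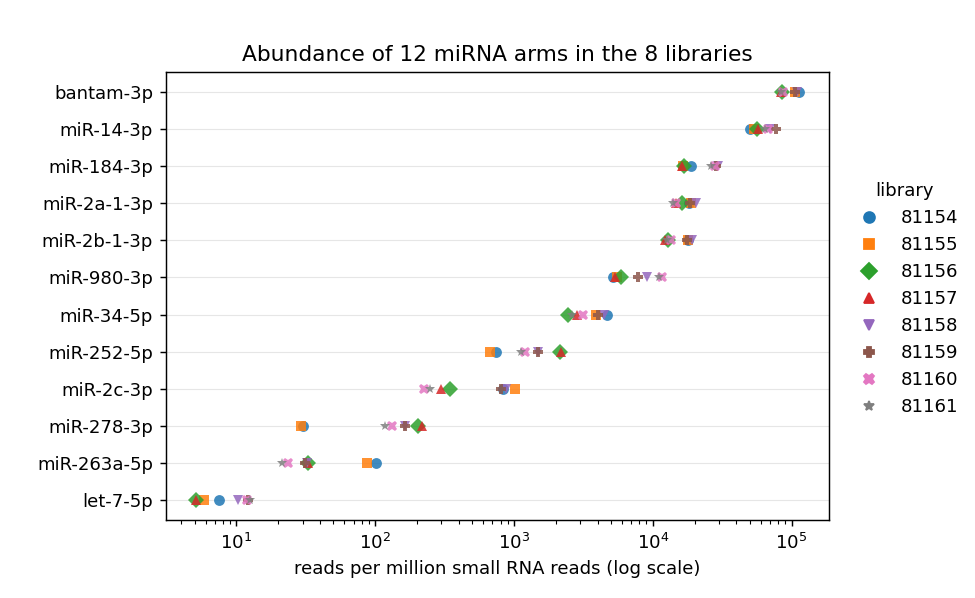
RPM (log scale) of 12 miRNA arms, with 1 symbol per library and no error bars. Bantam-3p is highest in each library, and miR-278-3p spans 7.38-fold, from 29.2 to 216 RPM.

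Most of the 100 arms spanned less than 2-fold in abundance between libraries. Over 100 arms the highest library exceeded the lowest by a median of 1.61-fold, and 30 arms reached 2-fold or more. miR-317-3p (4950 to 5478) and miR-11-3p (5464 to 6424) were among the steady arms. The widest span among these 100 arms was that of miR-278-3p, a regulator of growth and energy balance, with 7.38-fold between 29.2 RPM in library 81155 (780 reads) and 216 RPM in library 81157. Rarer arms spanned more, such as miR-92a-3p with 17.9-fold (0.786 to 14.1 RPM, 19 to 398 reads). Of the 7 among the 100 arms at 3-fold or more, miR-263a-5p spanned 4.81-fold (21.2 to 102), miR-1012-5p 4.56-fold (8.43 to 38.4) and miR-2c-3p 4.48-fold (225 to 1009). The others were miR-980-5p with 4.33-fold (70.6 to 305.4), miR-252-5p with 3.20-fold (676 to 2165) and miR-281-1-5p with 3.09-fold (6.82 to 21.1). Most miR-2c-3p reads were 20 nt long (60.0 to 72.0% per library). Paralogs such as miR-2a-3p can share reads with miR-2c-3p, so its span may not be one of miR-2c itself. Among more abundant arms, miR-996-3p spanned 2.64-fold (2358 to 6216) and miR-980-3p 2.25-fold (5145 to 11592). Median-of-ratios scaling would move library 81158 by 0.15 on the log2 scale and the others by less. With 1 value per library and no genotype attached, these spans have no replicate error.

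The reads of all arms together peaked at 22 nt, with a median share of 42.2% over the libraries. Reads of 23 nt made up 32.1% and reads of 24 nt 6.71% (5.33 to 8.09%). The mean length of these reads, each mature sequence counted once, was 22.14 to 22.30 nt. Its median was 22.25 nt and its counting SE at most 0.000413 nt. These were 5786498 to 10476352 reads per library, fewer than the miRNA reads given above. The share of reads of 24 nt or longer ran from 5.96% in library 81159 to 8.87% in library 81156.

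The 4 arms expected to be Nibbler substrates had wider ranges than the median of 0.210 nt over the 100 arms. Of them, 3 reached 0.5 nt and miR-263a-5p did not. miR-34-5p, a miRNA linked to ageing in flies, had mean lengths of 22.33 nt in library 81154, 22.24 in 81155, 23.74 in 81156, 23.82 in 81157, 22.57 in 81158, 22.51 in 81159, 23.89 in 81160 and 23.84 in 81161. Its range of 1.65 nt compares with a counting SE of at most 0.00606 nt and 45105 to 113319 reads per library. The hairpin lies at 3R, 10100936 to 10101034, plus strand, within an exon of lncRNA:CR43459, and the arm's seed is listed as TGGCAGTG. In library 81155 its most common length was 21 nt (32.0%, interval 31.7 to 32.3%). In library 81160 it was 24 nt (63.2%, interval 62.8 to 63.6%). Over the 8 libraries the share of 21 nt reads ran from 0.958 to 32.0% and that of 24 nt reads from 24.6 to 63.2%.

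miR-305-5p had mean lengths of 22.38 to 23.72 nt, a range of 1.34 nt. The share of 24 nt reads ran from 27.6 to 69.1% and that of 22 nt reads from 9.61 to 36.5%. Its hairpin lies at 2L, 7425972 to 7426044, plus strand, within no other annotated gene. miR-317-3p ranged by 1.196 nt, from 21.90 to 23.10 nt, with 17.53 to 42.5% of its reads at 24 nt. Its hairpin at 3R, 10091126 to 10091217, plus strand, is upstream of mir-34 and likewise within no other gene. miR-263a-5p ranged by 0.474 nt, from 23.36 to 23.84 nt. It was measured on only 364 to 2467 reads per library, with a counting SE of up to 0.0482 nt. This arm comes from mir-bft at 2L, 11953410 to 11953503, minus strand, within an exon of lncRNA:CR43314.

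**Figure D2:**
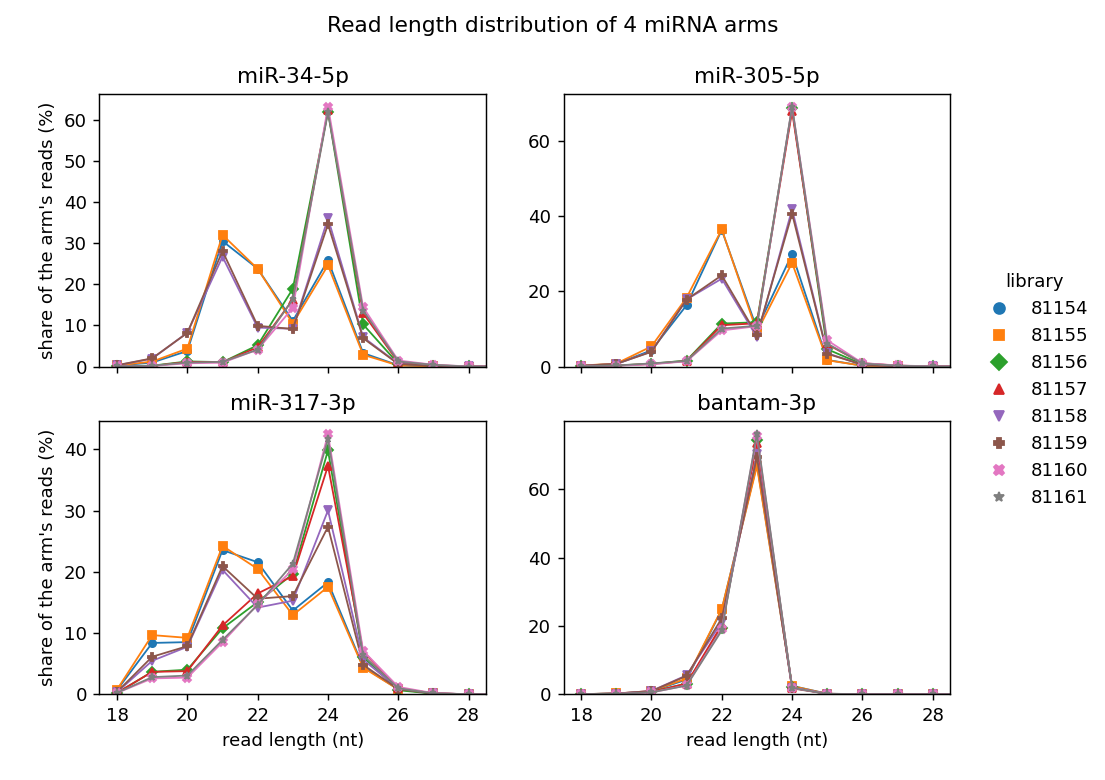
Share of each arm's reads (%) at each read length (nt) for miR-34-5p, miR-305-5p, miR-317-3p and bantam-3p, with 1 line per library. For miR-34-5p the 24 nt share runs from 24.6 to 63.2%, while the 23 nt share of bantam-3p stays between 66.8 and 76.1%.

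Among the 100 arms, 12 had a range of 0.5 nt or more and 23 had one under 0.1 nt. The median range was 0.210 nt, and in 90 arms the range exceeded 4 times the largest counting SE. Besides miR-34-5p, miR-305-5p and miR-317-3p, the wide arms were miR-12-5p (0.994 nt), miR-2b-3p (0.834), miR-2535b-5p (0.809), miR-2a-3p (0.705), miR-279-5p (0.688), miR-1002-5p (0.641), miR-7-5p (0.555), miR-281-1-5p (0.549) and miR-275-3p (0.514). For miR-279-5p the widest gap between libraries set off only 81156, at 23.98 nt against 24.24 nt or more in the others. For miR-281-1-5p it set off only 81155, at 22.19 nt against 22.40 nt or more. The related miR-281-2-5p, listed with another seed, ranged by only 0.130 nt at a median of 62.3 RPM. miR-12-5p lies in an intron of Gmap (X, 15509473 to 15509546, plus strand), and its 23 nt share ran from 46.0 to 87.4%. For miR-2a-3p the 24 nt share ran from 44.3 to 70.3%. For miR-7-5p, located in an intron of HnRNP-K (2R, 20606067 to 20606154, plus strand), it ran from 58.6 to 85.7%. Of the 36 arms with at least 1000 RPM, 11 had a range under 0.1 nt. Among them, miR-282-5p varied by 0.0508 nt around 21.76 nt and miR-33-5p by 0.0390 nt around 20.87 nt.

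Ranges in length differed within the lists. In the miR-2 family 2 of 8 arms reached a range of 0.5 nt, with miR-2b-3p at 0.834 nt and miR-13b-3p at 0.104 nt. In the cluster of miR-277, miR-317 and miR-34, 2 of 6 arms did, miR-34-5p and miR-317-3p. The opposite arm miR-34-3p ranged by 0.195 nt and miR-317-5p by 0.0990 nt. In the cluster of miR-275 and miR-305, 2 of 4 arms did, miR-305-5p and miR-275-3p, against 0.303 nt for miR-305-3p. In the cluster of miR-12, miR-283 and miR-304, 1 of 6 arms did, miR-12-5p. No arm over 10 RPM did so in the lists of mirtrons (0 of 5), of miR-9 and miR-79 (0 of 3), of miR-279 (0 of 2), or of bantam, miR-14 and miR-8 (0 of 3). The miR-279 list holds miR-279-3p and miR-996-3p above 10 RPM and does not include the wide arm miR-279-5p. Bantam-3p ranged by 0.114 nt (22.65 to 22.76 nt), miR-14-3p by 0.156 nt and miR-8-3p by 0.313 nt.

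**Figure D3:**
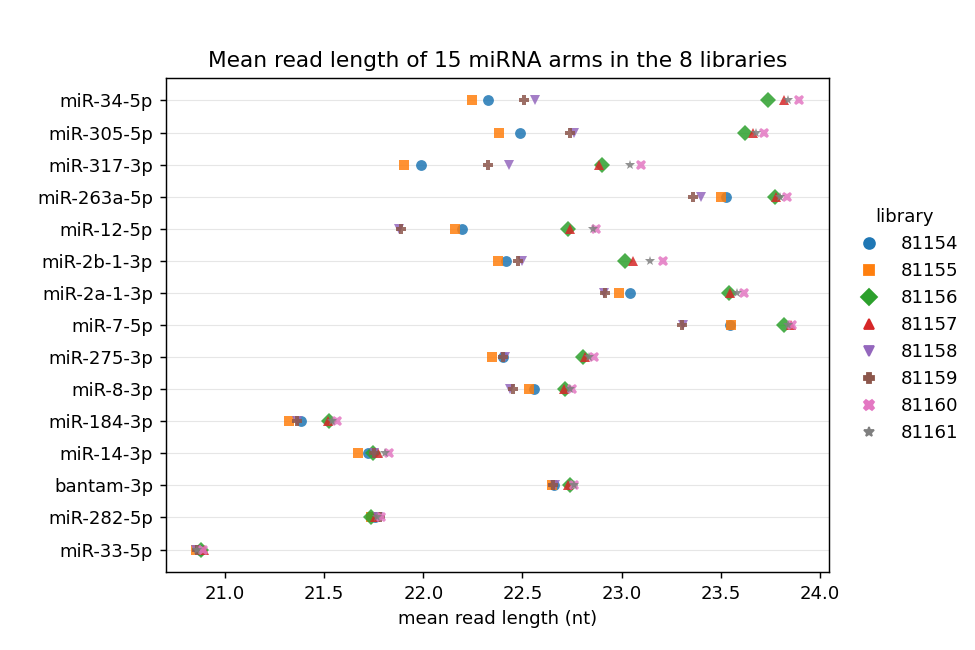
Mean read length (nt) of 15 miRNA arms, with 1 symbol per library; counting SEs are at most 0.0482 nt and not drawn. The values of miR-34-5p run from 22.24 to 23.89 nt, while those of miR-33-5p stay within 0.0390 nt.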

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

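The tests of errors at T bases, for the highest arms and across all arms, were chosen after the T-to-C shares were seen, and those of the 3 highest arms by library and of miR-13a-3p after the pooled shares but before their own results. The 8 libraries carry no genotype, so differences between genotypes could not be examined, and the groups of 2 are too small for a search for outlying samples. What stood out lies in the reads with a T-to-C mismatch, which are part of the read totals above and were not set apart there.

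In each library such reads exceeded the limit that a count of 0 allows. They made up 0.213% of arm reads in library 81154, 0.204% in 81155, 0.245% in 81156, 0.229% in 81157, 0.212% in 81158, 0.253% in 81159, 0.224% in 81160 and 0.231% in 81161. The median arm had 0.0905%. The library shares depend strongly on miR-14-3p, which held 74432 of these reads over the 8 libraries at a share of 0.638%. The next highest count was 14660, at bantam-3p. Leaving out 4 arms with shares above 10%, the share across arms rose with the number of T bases listed for the arm (96 arms, Spearman rho = 0.525, Pearson r = 0.382, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3e-05 over 3 tests). Arms are not independent replicates. The trend is consistent with errors at T bases in sequencing or copying, and other sources that scale with T bases stay open.

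Among the 100 arms, there were 3 at which nearly all reads carried the mismatch: miR-986-3p with 95.2% of 7529 reads, miR-4962-5p with 94.7% of 3124 reads and miR-4961-5p with 92.8% of 2321 reads. Among the 4 highest arms, the share per T base was 244.5 times that of the median arm or more. These arms were picked for their high shares, so a large ratio followed from the choice. The ratio shows how far they lie from the median arm, but as a test it cannot decide on sequencing errors. In the 3 arms the lowest share in any library was 90.5% (95% Wilson interval 86.8 to 93.3%, miR-4961-5p in library 81156), so the mismatch was near-complete in each of the 8 libraries. This is consistent with a difference between the genome of these cells and the reference, while reads from a related site stay open and no biological explanation was tested. The hairpins lie in an intron of Cyp4e2 (mir-986, 2R, 8444982 to 8445081), in an intron of Tlk (mir-4962, X, 3777382 to 3777505) and over an exon of ssx (mir-4961, X, 1373623 to 1373755).

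At miR-13a-3p 28.0% of 14726 reads carried the mismatch, between 24.01% in library 81161 and 32.9% in library 81159. Reads of its abundant paralog miR-13b-3p placed at miR-13a-3p could give this. If so, the mismatched reads would follow miR-13b-3p over the libraries. Their ratio to miR-13b-3p spanned 1.53-fold and their ratio to the other miR-13a-3p reads 1.55-fold, a difference of 0.0242 on the log2 scale against a counting error of 0.122, so this test leaves the source open. The mismatched reads were shorter (21.44 to 22.31 nt) than the other miR-13a-3p reads (22.68 to 22.83 nt) and than miR-13b-3p (22.73 to 22.84 nt). They also varied more between libraries. Their mean lengths were 21.57, 21.56, 21.54 and 21.44 nt in 81154, 81155, 81158 and 81159. In 81156, 81157, 81160 and 81161 they were 22.20, 22.18, 22.31 and 22.14 nt. The cause was not tested.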

How the results depend on the processing

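The tests between genotypes planned before the data were examined, with their alternatives, were not run, because the library numbers match no label. No paired analysis was possible because the libraries carry no replicate number either. Of the other alternatives, the equal weighting of arms, the length window and the omission of the top arm for the total length were planned, and the rest were chosen after seeing the data. The median over libraries of the mean length of the reads of all arms, each mature sequence counted once, was 22.25 nt. It became 22.04 nt with every arm weighted equally, 22.28 nt over 20 to 26 nt, 22.06 nt without bantam-3p, 22.31 nt with repeated loci counted as listed, and 22.21 to 22.28 nt with 1 library left out. The cause of these shifts was not tested. The number of arms with a length range of 0.5 nt or more was 12. It was 99 with no abundance filter, which adds arms with few reads, 8 at a mean of 100 RPM or more, 12 over 20 to 26 nt, 10 after each library's median shift was taken off, and 10 to 12 with 1 library left out. The number of arms with an abundance span of 2-fold or more was 30. It was 163 with no abundance filter, 28 with median-of-ratios scaling, and 23 to 30 with 1 library left out, the lowest without library 81154. For miR-34-5p the range of 1.65 nt became 1.60 nt over 20 to 26 nt and 1.48 nt after the median shift was taken off. With the same changes, in that order, 1.34 nt for miR-305-5p became 1.30 and 1.17 nt. For miR-317-3p, 1.196 nt became 0.971 and 1.03 nt, and for miR-263a-5p 0.474 nt became 0.426 and 0.393 nt. Depth limits the rarer arms: at 10 RPM a library holds 171 to 330 reads.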

Other observations

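The tests of a single shift, of a bias at 24 nt and of the 5p and guide arms were written before their results were seen. The tests of counting error and the choice of the 0.5 nt limit came after, and the mean lengths had been seen before any of them.

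The mean lengths of miR-34-5p fell into separate sets of values, with no library between 22.57 and 23.74 nt. The lower values belonged to libraries 81154 (22.33 nt), 81155 (22.24), 81158 (22.57) and 81159 (22.51), and the higher to 81156 (23.74), 81157 (23.82), 81160 (23.89) and 81161 (23.84). For miR-305-5p the values were 22.49, 22.38, 22.76 and 22.74 nt in the first 4 of these and 23.62, 23.66, 23.72 and 23.68 nt in the others. In 29 of the 100 arms, and in 10 of the 12 wide ones, the widest gap between neighbouring values parted the same libraries. The widest gap in abundance, on the log2 scale, parted the libraries in the same way in 9 of the 100 arms. All 9 were lower in 81156, 81157, 81160 and 81161, where miR-34-5p was longer. They were bantam-3p, miR-304-5p, miR-34-5p, miR-305-5p, miR-2a-3p, miR-2b-3p, miR-2c-3p, miR-13a-3p and miR-13b-3p. The miR-2 and miR-13 paralogs among them can share reads. Bantam-3p had 112468, 105511, 109893 and 105221 RPM in 81154, 81155, 81158 and 81159 and 85813, 83862, 87152 and 84631 in 81156, 81157, 81160 and 81161. In 25 arms the widest gap in abundance parted libraries 81154 to 81157 from 81158 to 81161, with the first 4 lower in 15 arms and higher in 10. Of the 15, miR-184-3p stood at 18819, 16542, 16699 and 16176 RPM in 81154 to 81157 and at 29563, 28678, 27918 and 26208 in 81158 to 81161. Of the 10, its opposite arm miR-184-5p had 1925, 2113, 2177 and 2066 in the first 4 and 1210, 1421, 1009 and 909 in the others. The other 66 arms parted in other ways. Of these, miR-278-3p had 30.4 and 29.2 in 81154 and 81155, 204 and 216 in 81156 and 81157, 164 and 164 in 81158 and 81159, and 133 and 117 in 81160 and 81161. In the read counts of arms with at least 20 reads in a pair of libraries, chi-square per degree of freedom was 104 between 81154 and 81155, 56.4 between 81156 and 81157, 106 between 81158 and 81159 and 21.7 between 81160 and 81161. The lowest of the other 24 pairs was 309.3, between 81159 and 81161. Which genotype any of these libraries holds is not given by the labels, and no library was assigned one from these values.

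For the 12 arms with a range of 0.5 nt or more, counting error is argued against in 11: with the reads split at random, the 11 arms reaching 0.5 nt in one part differed between the same libraries in the other part by more than 4 counting SEs (11 of 11, lowest 5.04). It is argued against as the whole cause for miR-281-1-5p, the other wide arm, as well: with its reads shuffled over the libraries, 4 of 100000 shuffles gave its range of 0.549 nt or more (permutation p = 5e-05, adjusted p = 0.00500 over 100 arms). The median shuffled range was 0.193 nt, so counting error can make up part of its range. In the part of the reads used to choose arms, 81156 and 81155 differed by 0.458 nt, under the limit, and in the other part by 0.609 nt. A single shift of all read lengths in a library, equal in every arm, is argued against as the whole cause. After each library's median shift was taken off, 10 of the 12 arms kept a range of 0.5 nt or more. Size selection that favours some lengths would move arms unequally, so this test cannot decide on it. A bias at 24 nt alike in all arms is argued against as the whole cause of changes in the 24 to 23 nt ratio. In 11 wide arms, 113% of the median range in the log2 ratio of 24 to 23 nt reads was left after the median over 49 other arms was taken off (0.93 before and 1.05 after). The 49 other arms themselves had a range of 0.66 in this ratio. The ratio leaves out all other read lengths, and a bias graded over length was not tested. At miR-34-5p this ratio was nearly the same in library 81159 (34.6% at 24 nt, 9.14% at 23 nt) and 81161 (61.8 and 16.3%). Its mean lengths there were 22.51 and 23.84 nt, so the ratio says little about the change in mean length of this arm. Nbr genotype, named by the design, stays open and untested, as do copies made by amplification and added 3' nucleotides, which read lengths alone do not tell from trimming.

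The width of the length range was not shown to depend on the arm of the hairpin. Its median was 0.210 nt in 50 5p arms and 0.212 nt in 50 3p arms (two-sided permutation p = 0.971, adjusted p = 0.971 over 3 tests). In 60 arms the tables call mature it was 0.257 nt, against 0.172 nt in 40 star arms (two-sided permutation p = 0.110, adjusted p = 0.165). The bound stated beforehand against a difference, a p of 0.05 or more, was wrong, because a missed threshold does not show equality. Both questions were therefore left open after the results were seen. Arms are not independent replicates.

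A second start position was listed for 18 arms, each under 10 RPM. The most abundant second position was that of miR-972-5p, whose positions 24 and 25 in the hairpin took 51.8 and 48.2% of its reads in the median library. Of the 162 arms under 10 RPM, 14 had a T-to-C share of 10% or more and 7 of 90% or more. These included miR-4943-5p with 90.6% and miR-4978-5p with 95.3%, besides let-7-5p with 74.6%, all named after their values were seen.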
